A study of Mus musculus with 8 samples.

How the data were processed

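Stranded mRNA libraries (TruSeq Stranded mRNA) were made from cultured mouse blood eosinophils. The labels give 8 samples in 4 groups of 2, which were used as labelled. CN (no cytokine) and E1 (15 ng/mL IFN-γ and TNF-α) came from one experiment. E0 (10 ng/mL IL-5) and E2 (10 ng/mL each of IL-5, GM-CSF and IL-4, with 30 ng/mL IL-33) came from a second one. Cells were enriched by magnetic depletion of CD90-positive and B220-positive cells to over 97% purity by stain, and cultured for 18 h. The labels do not say whether the 2 replicates of a group came from separate animals or separate cultures, and they give no sex. In every group replicate 1 held Y-linked transcripts and replicate 2 held Xist, so the spread between the replicates that the p-values measure includes a difference of sex. The protocol names IL-5 transgenic mice while the genotype label reads WT, and this was not resolved.

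The deposited table held raw read counts per Ensembl gene, with no normalization. The submitters' processing notes name STAR, featureCounts and the mm10 build. Tool versions, the annotation, the strand setting, the treatment of reads that map to several places and the filter on low counts are not given in the sources used here. The table had 15918 rows. Of these, 1 had no gene name and equalled the column totals, 100% of the counts of the named genes, and was left out. The other 15917 rows were genes, and the gene with the smallest total had 59 reads over the 8 libraries. Of the IDs, 15730 matched the symbol table and 187 did not, and these held 1.2% of the counts. Positions are from GENCODE M21 on mm10, a copy that may differ from the annotation behind the counts. The table held 12274 protein-coding genes and 0 mitochondrially encoded genes, so none of the 13 on that list could be measured.

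Library totals ran from 60809057 to 95065752 counts. A count of 0 in one library allowed up to 0.0316 to 0.0493 CPM, the level of 3 counts in that library. All intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. Where a group held 0 counts of a gene in all its libraries, the fold change is a lower bound against 3 counts over the group. With 1 to 3 counts in the group, the ratio is given with its exact 95% interval. Fitted fold changes of such genes are not printed. All other expression values are CPM with TMM scaling, as mean ± SD over the 2 libraries of a group (n = 2), and log2 fold changes are given ± their standard error (SE).

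Genes were tested in R 4.3.3 with edgeR 4.0.16. The steps were filterByExpr, TMM scaling, a model with 1 mean per group over all 8 libraries (4 residual degrees of freedom) and the quasi-likelihood F test, two-sided. The filter removed 4 genes and left 15913. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 5 contrasts were E1 versus CN, E2 versus E0, the difference of responses (E2 minus E0, minus the change from CN to E1), E2 versus E1 and E0 versus CN. The last 2 compare libraries of different experiments, so that group and experiment cannot be separated. Overlap between the first 2 contrasts, which share no library, was tested by Fisher's exact test, two-sided, in 4 direction pairs.

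The gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but the last one named below. There were 41 lists of 723 distinct genes, of which 644 were in the table: pathways and effector families, markers of other blood cells, and library checks. Some genes stand in several lists, so list results are not independent of each other. The 40 lists with at least 3 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, adjusted over the 40 lists. The same test with an estimated correlation was an alternative. Beside each list stand the members called over all genes and those called with p adjusted over the list alone. Medians of lists are log2 fold changes, and signs of median, mean and test are named where they differ.

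Genes named in the text were taken by rule. For E1 versus CN and E2 versus E0 these were the 12 largest changes each way among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups. For the other contrasts they were the first 6 each way, without the overlap condition for the difference of responses. Predicted genes without a proper symbol were passed over. From each list in the first 3 contrasts, up to 3 called members each way at 10 CPM or more were taken, or up to 2 with the highest level where none was called. A fixed set of 40 type 1, type 2, survival and eosinophil genes was added whatever its result, of which 39 were in the table.

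The pipeline was tested on simulated data with known changes placed in them. Counts were drawn from 1 mean per gene over all 8 libraries, the library totals and the fitted dispersions. The simulation held no difference between experiments or sexes and far fewer changed genes than were called in the data. The shares below hold for that simpler setting. In the layout of E1 versus CN, 76 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2 were called, and 4.9% of the calls were false. In that of E2 versus E0 the numbers were 72, 99 and 7.1%. A list of 20 genes shifted by 0.7 was called, and 0 of 39 unshifted lists were. The simulated genes were drawn independently of each other. The list result therefore does not test the preset correlation for lists whose genes vary together.

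The alternatives were DESeq2 size factors, library totals alone, no filter, a filter at 5 CPM, DESeq2 1.42.0, limma-voom, robust empirical Bayes, the 4 libraries of each contrast alone, an adjusted p below 0.01, a minimum log2 change of 1, the replicate number as a block, and each library left out in turn. A count without pseudogenes, sex-linked genes and ribosomal RNA loci was added after seeing the data. For it the filter, scaling and fit were repeated on the remaining genes. Library checks and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Reads were not used here, so alignment and counting were not repeated. Some genes and 1 list are not reported here.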

Results

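The series measured mRNA by sequencing in eosinophils, granule-bearing leukocytes of type 2 immunity, taken from the blood of C57BL/6 mice and cultured for 18 h. The protocol calls the mice IL-5 transgenic and the genotype label reads WT. There were 8 libraries in 4 groups of 2. In the first experiment the cells received no cytokine (CN) or 15 ng/mL of IFN-γ and TNF-α (E1). In the second, they received 10 ng/mL of IL-5 alone (E0) or 10 ng/mL of IL-5, GM-CSF and IL-4 with 30 ng/mL of IL-33 (E2). The replicate 1 and replicate 2 libraries held 95065752 and 83726309 counts in CN, 90578253 and 77623818 in E1, 60809057 and 78968527 in E0, and 82686185 and 75345693 in E2. Of the 15917 genes, 98.3% had counts in every library.

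Replicates ranked the genes alike, with Spearman correlations across genes of 0.992 to 0.9946, and each library counted as a separate sample. The common biological coefficient of variation was 0.1474. The first principal component held 57.8% of the variance and separated the 2 experiments. The next component, with 20.8%, separated E1 from CN and E2 from E0, and the fourth, with 5.2%, separated replicate 1 from replicate 2 in all 4 groups. The 10 most abundant genes took 5.77% to 9.94% of the counts, the highest share being in E0 replicate 1.

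Transcripts that IFN-γ and TNF-α changed in the eosinophil cultures were sought by comparing E1 with CN. Interferon-induced genes rose most. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), a guanylate-binding protein of cell-autonomous defence, rose from 2.36 ± 0.139 CPM in CN to 3286 ± 259 CPM in E1 (SD, n = 2 each), a log2 fold change of 10.44 ± 0.29 (adjusted p = 1.57e-07). Cxcl10 (chromosome 5, 92346638 to 92348889), a chemokine that attracts type 1 T cells through CXCR3, rose from 0.0948 ± 0.0151 to 189.7 ± 2.66 CPM (10.93 ± 0.21, adjusted p = 5.53e-08). Irf1 (chromosome 11, 53770014 to 53778374), an interferon-regulated transcription factor, rose 18.8-fold, and Cd274 (chromosome 19, 29367455 to 29388095), which encodes the inhibitory ligand PD-L1, rose 17.6-fold, from 52.5 ± 7.35 to 924 ± 18.6 CPM. Fn1, the gene of fibronectin, fell by 5.92 ± 0.43 on the log2 scale, Apoe, a lipid carrier, fell by 4.24 and Csf3r, the receptor of G-CSF, fell by 3.79. Csf3r also stands among the neutrophil markers. Whether a changed share of other cells in the cultures contributed to these falls was not tested.

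Of the 15913 genes tested, 2749 were called in E1 versus CN, 1463 higher and 1286 lower. Among them, 760 rose and 411 fell by at least 2-fold, and 243 rose and 54 fell by at least 8-fold. With library totals alone as the scaling, 1190 were higher and 1891 lower, so the higher share went from 53.2% to 38.6%. With the replicate number within each experiment as a block, 5515 were called, 2782 higher and 2733 lower. The lower genes were 743 without CN replicate 1 and 775 with the 4 libraries of the contrast alone. The other genes with the largest rises included Gbp2b (8.85), Rtp4 (8.61 ± 0.38), Gbp4 (8.30) and the paralog pairs Tgtp1 and Tgtp2 and Serpina3f and Serpina3g, whose reads can be shared between the copies. Cxcl9, which also signals through CXCR3, had 2 counts over both CN libraries and stood at a ratio of 2996 (95% interval 829 to 24741.5). Iigp1, with 0 counts in CN, was at least 2239.7-fold higher. Besides Fn1, Apoe and Csf3r, the largest falls were in the adhesion adaptor Tns1 (-4.02) and in 8 genes of the Ugt1a glucuronosyltransferase family, which share exons and fell alike (Ugt1a2, -3.27 to -3.34 over the family).

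**Figure D1:**
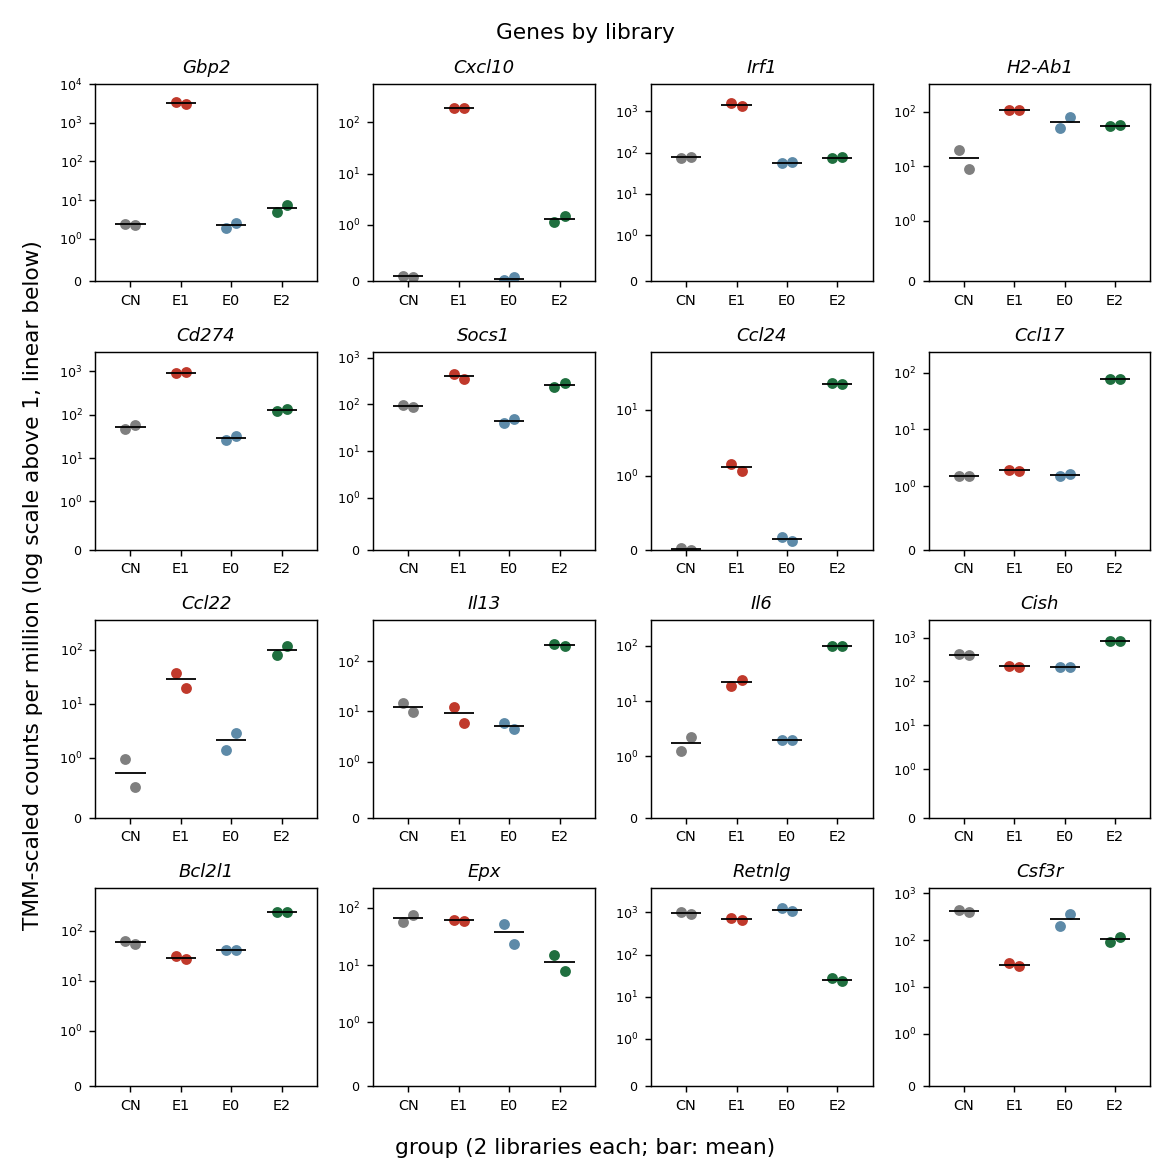
TMM-scaled CPM of 16 genes in each of the 8 libraries (points), by group, with the group mean as a bar. The vertical axis is logarithmic above 1 and linear below it. Gbp2 goes from a mean of 2.36 in CN to 3286 in E1, Ccl17 from 1.59 in E0 to 76.8 in E2, and Retnlg from 1163 in E0 to 25.4 in E2.

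The interferon programs rose as groups in E1. All 16 measured interferon-inducible GTPases rose (median 7.32, camera adjusted p = 3.81e-204), as did all 28 antiviral interferon-stimulated genes (median 4.21, adjusted p = 1.21e-96), among them Rtp4, Ifit1 (6.22) and the nucleic acid sensor Zbp1 (5.33). The counts were the same adjusted over the list alone. Of 20 interferon pathway regulators, 15 rose, 0 fell and 5 were not called (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.99e-48). The transcription factors Irf1 and Batf2 rose by 4.23 and 4.60, and Socs1, a feedback inhibitor of the pathway, by 2.08. These lists were also called with an estimated correlation (adjusted p = 0.00625, 0.0232 and 0.0134).

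Antigen presentation genes rose throughout. All 21 genes of MHC class I and the immunoproteasome rose (21 adjusted over the list alone, median 2.79, camera adjusted p = 5.48e-85, and 0.0232 with an estimated correlation), including H2-Q4 (3.96), and Nlrc5, the transactivator of class I genes from the regulator list, rose by 4.85. All 11 MHC class II genes rose (11 adjusted over the list alone, median 2.36, camera adjusted p = 2.46e-09, and 0.256 with an estimated correlation). Markers of monocytes, macrophages and dendritic cells were also called higher in this comparison (8 higher, 4 lower of 22, adjusted p = 0.0291, and 0.864 with an estimated correlation). H2-Ab1 (chromosome 17, 34257689 to 34269419) went from 14.1 ± 7.47 to 107 ± 1.82 CPM, H2-Eb1 rose by 3.05, and Ciita, which switches class II genes on, by 2.60. Of 16 costimulatory and checkpoint ligands, 8 rose, 1 fell and 7 were not called (10 and 3 adjusted over the list alone, camera adjusted p = 1.58e-05, and 0.265 with an estimated correlation). Cd40 rose by 6.42, Tnfsf14 rose by 0.75 and Icosl fell by 0.37, while Tnfsf4, with 0 counts in CN, was at least 21.9-fold higher.

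Inflammatory effectors rose with them. Of 25 NF-kappaB targets, 24 rose and 1 was not called (24 adjusted over the list alone, median 1.04, camera adjusted p = 1.92e-39, and 0.0166 with an estimated correlation). They included Ptgs2, the inducible cyclooxygenase (4.40), Ikbke (4.10), Tnfaip2 (4.07) and the adhesion molecule Icam1 (3.37). Of 11 type 1 and inflammatory cytokine genes, 7 rose and 4 were not called (8 rose adjusted over the list alone, median 1.46, camera adjusted p = 1.12e-07, and 0.0789 with an estimated correlation). Il12b, a subunit of IL-12, rose by 5.92, Nos2 (chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, rose by 4.13 from 2.68 ± 0.176 to 46.8 ± 15.8 CPM, and Tnf rose by 2.84.

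Among 12 pyroptosis and necroptosis genes, 7 rose and 5 were not called (8 rose adjusted over the list alone, camera adjusted p = 2.66e-13, and 0.0778 with an estimated correlation), with the inflammatory caspases Casp1 and Casp4 up by 2.95 and 2.87. Of 7 neutrophil and monocyte chemoattractants, 3 rose and 4 were not called (3 adjusted over the list alone, camera adjusted p = 0.0322, and 0.525 with an estimated correlation), namely Cxcl16 (2.90), Ccl9 (1.02) and Csf1 (0.62). Without E1 replicate 1 this list was not called (adjusted p = 0.0925). The 3 measured ligands of CCR3, CCR4 and CCR8, receptors of type 2 cells, were called higher (3 adjusted over the list alone, camera adjusted p = 0.000185, and 0.171 with an estimated correlation). Ccl22 rose by 5.22, and Ccl24, with 2 counts in CN, stood at a ratio of 120.2 (95% interval 32.9 to 999). Ccl17 had a log2 fold change of 0.34 and lost its call when any 1 library was left out (adjusted p = 0.0584 to 0.175).

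Apart from these ligands, the lists of type 2 biology and of eosinophil identity were not called in E1 versus CN. Of 9 type 2 and regulatory cytokine genes, 2 rose, Il6 by 3.63 and Il1rn, the IL-1 receptor antagonist, by 0.61, and Tgfb1 fell by 0.42 (adjusted p = 0.605, with a median of -0.29 against an upward test). Il13 (-0.42) and Il4 (0.06) were not called, and Il13 was called lower without E1 replicate 1 (-1.05, adjusted p = 0.0281). The STAT6 and alternative activation list had 10 genes higher, 7 lower and 12 not called (adjusted p = 0.543, with a negative median against an upward test), from Tgm2 (3.08) to Fn1. In the list of STAT5 targets, 5 rose, 7 fell and 10 were not called (adjusted p = 0.724, with a mean of 0.03 and a median of -0.19). The survival gene Bcl2 fell by 2.21 (chromosome 1, 106538178 to 106714274), Bcl2l1, which encodes BCL-XL, by 1.04, and Cish, a feedback inhibitor of cytokine receptors, by 0.89. The 15 genes of IL-33 receptor and IL-1 family signalling had 3 higher, 7 lower and 5 not called (adjusted p = 0.177), with Il1rl1, the IL-33 receptor, lower by a log2 fold change of -0.49. None of 8 granule protein genes was called (adjusted p = 0.729), with Epx, eosinophil peroxidase, at -0.10 ± 0.38 and Prg2, major basic protein, at -0.14 ± 0.29, and 27 of 33 eosinophil surface receptors were not called (3 higher, 3 lower, adjusted p = 0.605), including Ccr3 (-0.03) and Il5ra (0.07). In the order given, these 6 lists had 2 and 1, 12 and 8, 6 and 9, 5 and 8, 0 and 0, and 3 and 3 genes higher and lower when adjusted over the list alone. All these counts are from the model without a block, whose spread includes the difference of sex. With the replicate number within each experiment as a block, 5515 genes were called instead of 2749. None of these 6 lists was called with it, but Il13 was called lower. A gene not called here is thus not shown to be unchanged.

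Of 19 tissue remodelling and growth factor genes, 2 rose, 9 fell and 8 were not called (3 and 9 adjusted over the list alone, median -0.45, camera adjusted p = 0.0166, and 0.297 with an estimated correlation). The collagenase Mmp8 fell by 2.85 and Hbegf by 2.04, while Mmp14 rose by 4.07, and Igf1, with 1 count in E1, was lower by a ratio of 135 (95% interval 23.9 to 5364). Among 18 pro-apoptotic genes, 6 rose and 1 fell (adjusted p = 0.142), with Bak1 up by 1.21 and the TNF receptor Tnfrsf1a by 1.04. The 14 anti-apoptotic genes split into 4 higher and 3 lower (adjusted p = 0.729), with Birc3 up by 1.05. Prostaglandin and leukotriene synthesis (3 higher, 4 lower of 15, adjusted p = 0.848), glycolysis and hypoxia (4 and 2 of 26, adjusted p = 0.667), MYC and ribosome biogenesis (2 and 1 of 26, adjusted p = 0.667), the unfolded protein response (1 and 2 of 22, adjusted p = 0.729), lineage transcription factors (0 and 2 of 13, adjusted p = 0.171) and the cell cycle (0 and 0 of 22, adjusted p = 0.667) were not called either. Adjusted over the list alone, these 8 lists from the pro-apoptotic genes onwards had 6 and 3, 5 and 4, 4 and 5, 5 and 2, 2 and 1, 4 and 4, 0 and 2, and 0 and 0 genes higher and lower.

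Further metabolic and early response lists in E1 versus CN were called only under alternatives. Oxidative phosphorylation (4 higher of 31, adjusted p = 0.0892) was called higher without CN replicate 1 (0.0202) or E1 replicate 2 (0.00784) and by camera on limma-voom values (0.000103). Cholesterol biosynthesis (1 higher of 23, Mvd at 0.81, median -0.43, adjusted p = 0.367) was called lower without CN replicate 2 (8.9956e-05) or E1 replicate 1 (0.0249). Immediate early genes (6 higher of 18, among them Atf3 at 1.66, adjusted p = 0.161) were called higher without CN replicate 2 (0.0488) and by camera on limma-voom values (0.0386). Cytosolic ribosomal proteins (6 higher of 30, adjusted p = 0.0517) were called higher with DESeq2 size factors (0.0433), by camera on limma-voom values (7.53e-06) and without CN replicate 2 (0.00655) or E1 replicate 2 (0.0226). Adjusted over the list alone, the higher and lower genes of the 4 lists were 4 and 0, 1 and 0, 6 and 2, and 6 and 0.

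Markers of other leukocytes also moved between CN and E1. Of 22 monocyte, macrophage and dendritic cell markers, 8 rose, 4 fell and 10 were not called (10 and 5 adjusted over the list alone, camera adjusted p = 0.0291, and 0.864 with an estimated correlation). Ly6c2 (chromosome 15, 75108158 to 75111970) rose 40.4-fold from 99.0 ± 8.74 to 3999 ± 304 CPM, Cd14 by 2.44 and Csf1r by 0.84. This call was lost without CN replicate 2 (adjusted p = 0.2296) and without E1 replicate 2 (0.0805). Of 16 neutrophil markers, 1 rose, 8 fell and 7 were not called (2 and 9 adjusted over the list alone, camera adjusted p = 0.0236, and 0.729 with an estimated correlation). Csf3r and the chemokine receptor Cxcr2 (-2.72) fell and Ly6g rose by 3.21, and the list was not called without E1 replicate 2 (adjusted p = 0.168). T cell (0 of 11 called, adjusted p = 0.999), B cell (1 higher of 15, Cd22, adjusted p = 0.667), NK cell (1 lower of 12, adjusted p = 0.366), basophil and mast cell (2 higher, 2 lower of 10, adjusted p = 0.729), platelet (1 lower of 5, adjusted p = 0.724), erythroid (0 of 6, adjusted p = 0.999) and sex-linked (0 of 5, adjusted p = 0.928) genes were not called as lists. Medians and means differed in sign for the T cell (-0.06 and 0.10) and B cell (-0.02 and 0.22) markers and for the unfolded protein response (-0.03 and 0.01). Called genes adjusted over the list alone were 0, 1, 1, 5, 3, 0 and 0 in the 7 uncalled marker lists.

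Cells given GM-CSF, IL-4 and IL-33 on top of IL-5 (E2) were compared with cells given IL-5 alone (E0), to find what the type 2 cytokines added. Chemokines and cytokines of type 2 immunity were among the genes with the largest rises. Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049), eotaxin-2, rose from 0.148 ± 0.0408 to 24.6 ± 0.186 CPM (log2 fold change 7.39 ± 0.30, adjusted p = 2.45e-06). Ccl17 (chromosome 8, 94810453 to 94812036), a CCR4 ligand, rose from 1.59 ± 0.0835 to 76.8 ± 0.721 CPM (5.59 ± 0.10, adjusted p = 7.21e-08), and Il13 (chromosome 11, 53631324 to 53634702), a central type 2 cytokine, from 5.17 ± 0.949 to 208 ± 15.1 CPM (5.33 ± 0.37, adjusted p = 3.07e-05). Il6 (chromosome 5, 30013114 to 30019981) rose 49.3-fold. Retnlg (chromosome 16, 48872621 to 48874496), a resistin-like protein gene of granulocytes, fell from 1163 ± 135 to 25.4 ± 2.97 CPM (-5.52 ± 0.15, adjusted p = 5.89e-07).

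Between E0 and E2, 5655 genes were called, 2711 higher and 2944 lower, of which 828 rose and 943 fell by at least 2-fold. The count fell to 3562 without E0 replicate 1, to 3567 without E2 replicate 1 and to 3334 without E2 replicate 2. With the replicate number within each experiment as a block, 8507 genes were called. With pseudogenes, sex-linked genes and ribosomal RNA loci left out and the scaling and fit repeated, 3041 were higher and 2765 lower. The higher share thus went from 47.9% to 52.4%. Dropping genes cannot by itself raise the number of higher genes, so part of this shift came from the repeated scaling and fit. The other large rises included Plet1 (7.57 ± 0.22, chromosome 9, 50494525 to 50505482), which overlaps the antisense gene Plet1os, the vitamin D receptor gene Vdr (6.72), the imprinted gene Peg10 (6.32), the activation marker Cd69 (5.41) and the transcription factor gene Pou2f2 (5.29). Large falls were seen in Apoe (-5.42), Pbld2 (-5.07), the fractalkine receptor gene Cx3cr1 (-4.59), the scavenger receptor gene Stab1 (-3.93) and the metalloproteinase genes Mmp8 (-3.55) and Mmp27 (-3.45). Cx3cr1 also stands among the monocyte, macrophage and dendritic cell markers and Mmp8 among the neutrophil markers. Whether a lower share of monocytes or macrophages contributed to these falls was not tested.

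Type 2 programs rose as groups in E2. Of 9 type 2 and regulatory cytokine genes, 8 rose and 1, Il4 (0.14), was not called (8 adjusted over the list alone, median 1.65, camera adjusted p = 9.11e-14, and 0.0553 with an estimated correlation). Ebi3 rose by 1.92 and Csf2, the gene of GM-CSF, with 0 counts in E0, was at least 123-fold higher. Markers of basophils and mast cells were also called higher in this comparison (5 of 10 higher, 0 lower, adjusted p = 0.00346, and 0.257 with an estimated correlation). The 3 measured ligands of CCR3, CCR4 and CCR8 rose (3 adjusted over the list alone, median 5.59, camera adjusted p = 4.35e-23, and 0.0294 with an estimated correlation), with Ccl22 (chromosome 8, 94745590 to 94751699) up by 5.53 ± 0.47. These ligands, Ccl17, Ccl22 and Ccl24, also stand in the STAT6 and alternative activation list, so the results of these lists share genes. Of 29 STAT6 and alternative activation genes, 18 rose, 7 fell and 4 were not called (19 and 7 adjusted over the list alone, median 1.96, camera adjusted p = 2.21e-16, and 0.0354 with an estimated correlation). Chil3, the chitinase-like protein Ym1, rose by 4.80, the checkpoint ligand gene Pdcd1lg2 by 2.50 and the IL-4 receptor gene Il4ra by 1.69, Alox15, a lipoxygenase gene, fell by 0.68, and Retnla was not called (0.98 ± 0.38, adjusted p = 0.0777). Retnla was called with the 4 libraries of the contrast alone (0.99, adjusted p = 0.00671) and with the replicate number within each experiment as a block.

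STAT5 targets and anti-apoptotic genes rose too. Of 22 STAT5 targets, 17 rose, 2 fell and 3 were not called (17 and 2 adjusted over the list alone, median 1.49, camera adjusted p = 3.25e-24, and 0.0868 with an estimated correlation). The kinase gene Pim2 rose by 3.88, the cyclin gene Ccnd2 by 3.17, Socs1 by 2.54 and Cish by 1.96, and Csf2rb2, a paralog of the common receptor chain of IL-5 and GM-CSF, fell by 0.51. Of 14 anti-apoptotic genes, 11 rose and 3 were not called (11 rose and 1 fell adjusted over the list alone, median 1.10, camera adjusted p = 3.25e-18, and 0.0294 with an estimated correlation). Of this list, Bcl2, Bcl2l1, Mcl1, Pim1 and Pim2 also stand among the STAT5 targets, and Birc2, Birc3 and Cflar among the NF-kappaB targets. Bcl2l1 (chromosome 2, 152780668 to 152831728) rose 5.91-fold from 40.9 ± 0.176 to 241.3 ± 0.744 CPM, and Mcl1 was not called (-0.11). The 18 pro-apoptotic genes had 4 higher and 3 lower (adjusted p = 0.947, the mean was below 0 and the median above it), with the death receptor gene Fas up by 1.41 and Bbc3 (-1.11) lower (4 and 3 adjusted over the list alone).

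Inflammatory signalling rose in E2 as well. Of 25 NF-kappaB targets, 23 rose and 2 were not called (23 rose and 1 fell adjusted over the list alone, median 1.42, camera adjusted p = 1.41e-46, and 0.0294 with an estimated correlation), including Ikbke (4.12), Traf1 (3.75) and the inhibitor gene Nfkbia (3.34). Cxcl10 rose by 4.55. Of 15 genes of IL-33 receptor and IL-1 family signalling, 7 rose, 4 fell and 4 were not called (7 and 4 adjusted over the list alone, camera adjusted p = 0.00775, and 0.257 with an estimated correlation). The brake Irak3 rose by 3.45, Il1rn by 1.31 and Il1rl1 by 0.51, and Il18r1 fell by 0.88. Of 11 type 1 and inflammatory cytokine genes, 7 rose, 3 fell and 1 was not called (7 and 4 adjusted over the list alone, camera adjusted p = 0.00228, and 0.257 with an estimated correlation), with Il1a up by 4.86, Tnf by 4.04 and Il1b by 2.29, while Nos2 was the gene not called (-1.09), though it was called lower by DESeq2 (adjusted p = 0.0118) and without E1 replicate 1 (0.0442) or E1 replicate 2 (0.0474). The cytokine list was not called without E0 replicate 1 (adjusted p = 0.0587), and neither it nor the IL-33 list was called by camera on limma-voom values.

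The interferon and antigen presentation lists had smaller medians in E2 versus E0 than in E1 versus CN, or were not called. Of 16 interferon-inducible GTPases, 8 rose and 8 were not called (11 rose adjusted over the list alone, median 0.89, camera adjusted p = 0.000138, and 0.436 with an estimated correlation), with Irgm2 up by 0.53. Of 20 interferon pathway regulators, 13 rose, 3 fell and 4 were not called (14 and 4 adjusted over the list alone, camera adjusted p = 0.00119, and 0.265 with an estimated correlation), with Irf5 up by 1.16 and Nlrc5 by 1.02 and Jak1 at -0.46. The 28 antiviral genes had 3 higher, 6 lower and 19 not called (3 and 6 adjusted over the list alone, adjusted p = 0.991). MHC class I (4 higher, 2 lower of 21, adjusted p = 0.680) and class II (1 higher, 2 lower of 11, 0.991, median 0.10, mean -0.09) were not called, and Ciita stood at 0.10, with the counts unchanged when adjusted over the list alone. Of 16 costimulatory and checkpoint ligands, 8 rose, 1 fell and 7 were not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.000233, and 0.265 with an estimated correlation), with Cd274 up by 2.14 and Cd80 by 1.54. Of 12 pyroptosis and necroptosis genes, 6 rose and 6 were not called (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0003, and 0.265 with an estimated correlation), with Zbp1 up by 2.49, Ripk3 by 2.26 and Casp4 by 1.94.

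Genes of eosinophil identity fell or were mixed. Of 8 granule protein genes, 6 fell, 1 rose and 1 was not called (6 and 1 adjusted over the list alone, median -1.61, camera adjusted p = 0.0316, and 0.540 with an estimated correlation). Ear1, an eosinophil ribonuclease, fell from 92.4 ± 46.2 to 14.3 ± 10.4 CPM and Prg3 fell by 2.29. The list was not called without E0 replicate 1 (adjusted p = 0.0774). Epx (chromosome 11, 87864000 to 87875536) went from 38.3 ± 21 to 11.5 ± 5.2 CPM (adjusted p = 0.0115) and was not called without E0 replicate 1 (0.0611) or E2 replicate 2 (0.0767). Prg2 and Ear2 were lost in the same way (0.121 and 0.127, and 0.0580 and 0.0605). Among 33 surface receptors, 9 rose, 14 fell and 10 were not called (10 and 14 adjusted over the list alone, adjusted p = 0.583). Ccr3, the eotaxin receptor, fell from 2576 ± 20.6 to 1254 ± 89.2 CPM, the chemokine receptor Cxcr4 fell by 1.46 and the integrin Itga4 by 1.27, while Siglece rose by 2.64. The 13 lineage transcription factors had 6 higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.542), with Xbp1 up by 1.45 and Ikzf2 (-1.84) and Cebpa (-1.45) lower.

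**Figure D2:**
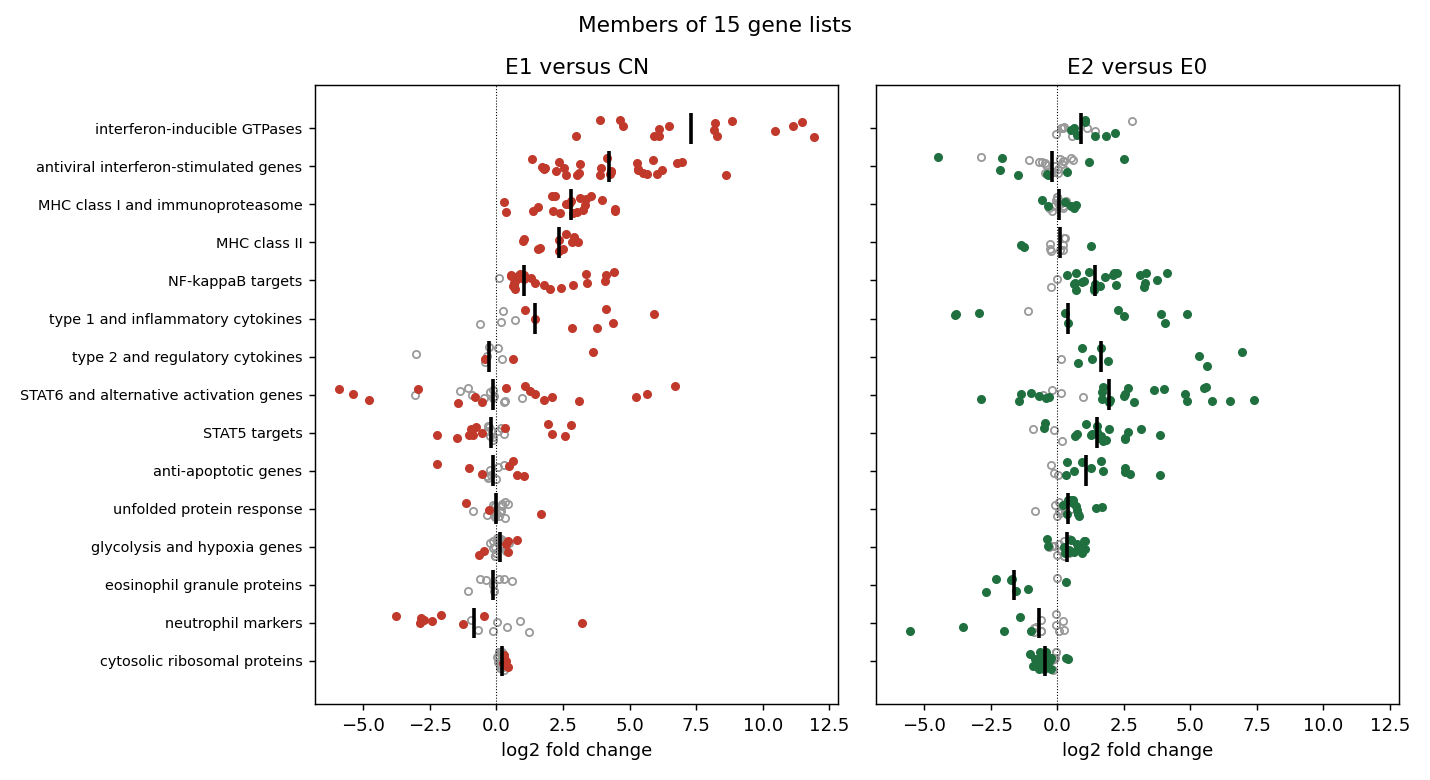
Log2 fold change of each measured gene (points) in 15 of the lists for E1 versus CN and for E2 versus E0, with the list median as a bar. Filled points were called and open points were not, and genes with a group at 0 are drawn at their bound. The interferon-inducible GTPases have a median of 7.32 in E1 versus CN and 0.89 in E2 versus E0, and the STAT5 targets -0.19 and 1.49.

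Metabolic and biosynthetic lists went different ways in E2. Of 26 glycolysis and hypoxia genes, 13 rose, 2 fell and 11 were not called (15 and 3 adjusted over the list alone, camera adjusted p = 0.000771, and 0.538 with an estimated correlation). Pgk1 rose by 1.04 (it has retrocopies that can share its reads), Egln3 by 1.03 and Pfkp by 1.02. Of 22 unfolded protein response genes, 12 rose and 10 were not called (12 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00024, and 0.265 with an estimated correlation), with Xbp1, the chaperone gene Hyou1 (0.82) and Atf4 (0.78) higher. Of 26 MYC and ribosome biogenesis genes, 12 rose and 14 were not called (12 adjusted over the list alone, camera adjusted p = 0.0135, and 0.763 with an estimated correlation). By contrast, of 30 cytosolic ribosomal protein genes, whose retrocopies can share their reads, 22 fell, 2 rose and 6 were not called (23 and 2 adjusted over the list alone, median -0.44, camera adjusted p = 1.13e-05, and 0.570 with an estimated correlation). Of 18 immediate early genes, 7 rose, 4 fell and 7 were not called (7 and 4 adjusted over the list alone, camera adjusted p = 0.0316, and 0.540 with an estimated correlation), with Ier3 up by 2.41, Egr1 by 2.15 and Fos at -1.33. That list was not called without E0 replicate 1 (adjusted p = 0.0651) or E2 replicate 2 (0.0575), nor by camera on limma-voom values.

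Lists with members moving both ways in E2 included tissue remodelling and growth factors, with 9 higher, 6 lower and 4 not called of 19 (10 and 8 adjusted over the list alone, adjusted p = 0.448). The elastase gene Mmp12 rose by 2.57, Hbegf by 2.03 and the urokinase receptor gene Plaur by 1.40, while Mmp8 and Mmp9 (-0.96) fell. In prostaglandin and leukotriene synthesis, 3 rose and 4 fell of 15 (adjusted p = 0.930), with Ptgs1 up by 1.17 and Alox5ap at -0.53, and Hpgd, with 0 counts in E2, was at least 71.9-fold lower. Of 7 neutrophil and monocyte chemoattractants, 2 rose, with Ccl9 at 1.61, and Csf1 fell by 1.63 (adjusted p = 0.697). Oxidative phosphorylation (6 higher, 2 lower of 31, adjusted p = 0.134) was called higher by camera on limma-voom values. Cholesterol biosynthesis (1 and 1 of 23, adjusted p = 0.819) and the cell cycle (3 and 0 of 22, adjusted p = 0.448) were not called. Adjusted over the list alone, these 5 lists from prostaglandin synthesis onwards had 3 and 4, 2 and 1, 5 and 2, 1 and 1, and 2 and 0 genes higher and lower.

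Markers of other leukocytes differed between E0 and E2. Of 16 neutrophil markers, 5 fell and 11 were not called (5 adjusted over the list alone, median -0.70, camera adjusted p = 6.97e-06, and 0.265 with an estimated correlation). Retnlg, Mmp8 and Csf3r (-1.40) fell, and the abundant transcripts S100a8 (-0.62 ± 0.34) and S100a9 (-0.86 ± 0.32) were not called. Of 22 monocyte, macrophage and dendritic cell markers, 11 fell, 6 rose and 5 were not called (13 and 6 adjusted over the list alone, median -1.09, camera adjusted p = 0.0316, and 0.805 with an estimated correlation). Cx3cr1, Lyz2 (-2.25) and Ly6c2 (-1.32) fell while Csf1r rose by 0.93, and the list was not called without E0 replicate 2 (adjusted p = 0.0927) or by camera on limma-voom values. Of 10 basophil and mast cell markers, 5 rose and 5 were not called (5 adjusted over the list alone, median 0.61, camera adjusted p = 0.00346, and 0.257 with an estimated correlation), with Cd200r3 up by 2.31 and Cyp11a1 by 1.56. T cell (2 higher, 2 lower of 11, adjusted p = 0.947), B cell (3 and 2 of 15, adjusted p = 0.680), NK cell (3 and 3 of 12, adjusted p = 0.930), platelet (1 and 1 of 5, adjusted p = 0.991), erythroid (1 and 0 of 6, adjusted p = 0.930) and sex-linked (0 of 5, adjusted p = 0.991) genes were not called as lists, though the granzyme genes Gzmb and Gzma rose by 4.30 and 1.29 and Cd22 by 2.69. For the NK cell markers the median was -0.23 and the mean 0.07, and for the erythroid markers both were negative against an upward test (median -0.84). Adjusted over the list alone, the counts of these 6 marker lists were the same.

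The overlap of the 2 responses was then tested, each response having its own control libraries. Among genes higher in E1, 557 were also higher in E2, against 249.2 if independent (odds ratio 3.51, 95% interval 3.12 to 3.94, Fisher's exact test, adjusted p = 2.39e-91). Lower in both were 404 genes against 237.9 (odds ratio 2.18, adjusted p = 3.26e-31 by the exact test). Opposite changes were also found: 338 genes fell in E1 and rose in E2, against 219.1 (odds ratio 1.84, exact adjusted p = 3.50e-18), and 247 did the reverse, against 270.7 (exact adjusted p = 0.0968). The counts if independent treat all genes as equally easy to call. Of processed pseudogenes 4.6% and 8.6% were called in the 2 contrasts, against 19.6% and 40.2% of protein-coding genes. Both contrasts also share 1 estimate of spread per gene. Part of an excess in either direction can come from this, so these p-values alone do not show a shared or opposed response. In all, 961 genes changed the same way and 585 in opposite ways, or 2271 and 1493 with the replicate number within each experiment as a block. Without E2 replicate 2 these were 629 and 375, and without E2 replicate 1, 346 changed in opposite ways. Icam1, Ikbke, Ccl22, Socs1 and Cd274 rose in both, while Bcl2l1, Cish and Hbegf fell in E1 and rose in E2, and Ly6c2 rose in E1 and fell in E2. Across genes, which are not independent replicates, the log2 fold changes had Pearson and Spearman correlations of 0.205 and 0.147.

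**Figure D3:**
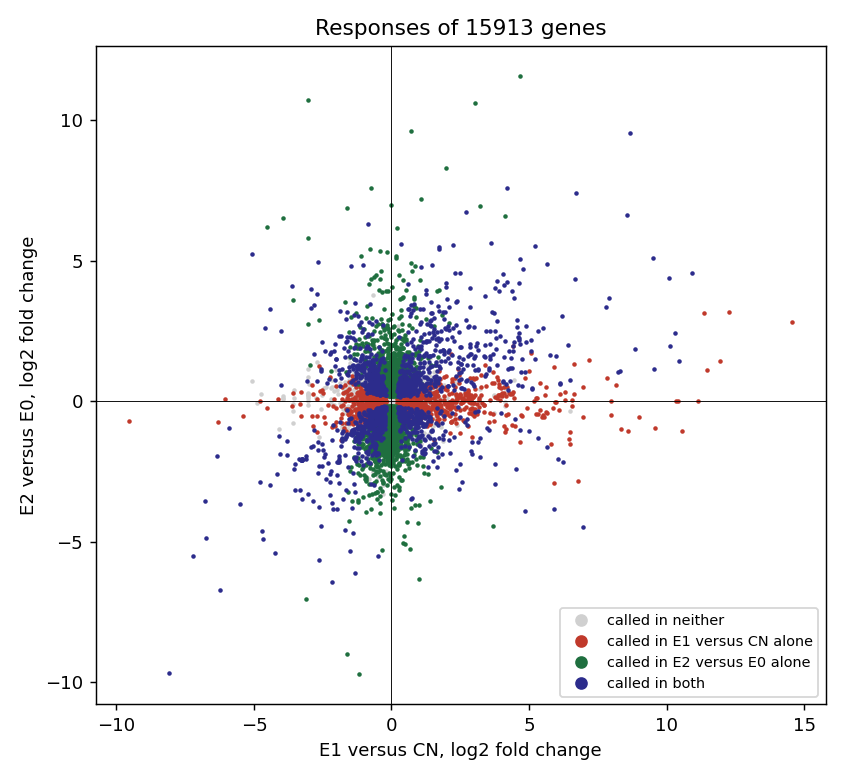
Log2 fold change of 15913 genes (points) in E1 versus CN on the horizontal axis against E2 versus E0 on the vertical axis, coloured by whether a gene was called in neither, in 1 or in both. The fitted values of genes near 0 counts in a group are not bounds. Pearson's correlation across genes is 0.205, with 961 genes called in the same direction and 585 in opposite directions.

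The difference of responses asked which genes moved further with the type 2 cytokines than with IFN-γ and TNF-α. The controls differed too, since E0 held IL-5 and CN did not. Interferon genes had the largest negative differences and type 2 and survival genes were among the positive ones. Irf1 differed by -3.82, Nos2 by -5.22 and Ciita by -2.51 on the log2 scale. Il13 differed by 5.75, Ccl17 by 5.25, Chil3 by 6.26, Bcl2 by 3.95, Bcl2l1 by 3.60 and Cish by 2.85. In total, 4018 genes were called, 1798 more positive with the type 2 cytokines and 2220 more negative, and the positive ones were 1177 without E2 replicate 1 and 1193 without E2 replicate 2. With library totals alone, 2138 were positive and 1866 negative, so the positive share went from 44.7% to 53.4%. With the replicate number within each experiment as a block, 6816 genes were called, 3219 positive and 3597 negative. Plet1 (8.30), Lipg, an endothelial lipase (7.60), Peg10 (7.16), the lectin gene Mgl2 (6.94) and Ccn3 (6.24) also had large positive differences, and Tgtp2 (-10.36), Il12b (-9.75) and Rtp4 (-9.66) large negative ones.

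By list, the difference was negative for all 16 interferon-inducible GTPases (16 adjusted over the list alone, median -6.48, camera adjusted p = 9.08e-96) and all 28 antiviral genes (28 adjusted over the list alone, median -3.75, camera adjusted p = 5.27e-60), with adjusted p = 0.0681 and 0.0709 with an estimated correlation. It was negative for 19 of 21 MHC class I genes, with 1 positive (19 and 1 adjusted over the list alone, camera adjusted p = 1.02e-49), 9 of 11 class II genes (9 adjusted over the list alone, camera adjusted p = 3.9e-06) and 12 of 20 pathway regulators (12 and 1 positive adjusted over the list alone, camera adjusted p = 3.92e-19). For these 3 lists the adjusted p = 0.0709, 0.396 and 0.0709 with an estimated correlation. It was positive for 14 of 22 STAT5 targets (14 and 2 negative adjusted over the list alone, camera adjusted p = 2.12e-17), 8 of 14 anti-apoptotic genes, with 3 negative (8 and 4 adjusted over the list alone, camera adjusted p = 2.34e-13), 8 of 9 type 2 and regulatory cytokine genes (8 adjusted over the list alone, camera adjusted p = 2.19e-07), 13 of 29 STAT6 and alternative activation genes, with 1 negative (14 and 2 adjusted over the list alone, camera adjusted p = 6.41e-08) and 8 of 15 IL-33 and IL-1 family genes, with 1 negative (8 and 1 adjusted over the list alone, camera adjusted p = 0.000582). The cytokine list also holds regulatory genes such as Il6, Il1rn and Ebi3, and Il4 was its member not called. Of these 5 lists, the anti-apoptotic genes had adjusted p = 0.0681 and the others 0.122 with an estimated correlation. With an estimated correlation, camera called 0 of 40 lists for this contrast (smallest adjusted p = 0.0681 with an estimated correlation), and 10 lists had an unadjusted p under 0.05. The test fry, not among the listed alternatives, called 18 lists here, 15 in E1 versus CN and 20 in E2 versus E0. It tests whether a list's genes move, on balance, one way, and not whether they move more than other genes. It thus answers another question than camera.

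Further lists called were the pyroptosis and necroptosis genes (6 of 12 negative, 1 positive, adjusted p = 0.00573, and 0.461 with an estimated correlation) and the unfolded protein response (8 of 22 positive, 1 negative, Xbp1 at 2.59, adjusted p = 0.00144, and 0.410 with an estimated correlation). Tissue remodelling genes had 8 positive and 2 negative of 19, with Hbegf at 4.07 (adjusted p = 0.00775, and 0.299 with an estimated correlation), and were not called by camera on limma-voom values. Ribosomal proteins were negative for 25 of 30 (adjusted p = 4.97e-07, and 0.555 with an estimated correlation) and monocyte markers for 10 of 22 and positive for 2, with Ly6c2 at -6.66 (adjusted p = 0.000244, and 0.555 with an estimated correlation). Of the 3 ligands of CCR3, CCR4 and CCR8, only Ccl17 was called (adjusted p = 0.000108, and 0.187 with an estimated correlation), and Ccl22 had a difference of 0.30, or -0.26 without CN replicate 1. The third, Ccl24, had 2 counts in CN, and the list was not called by camera on limma-voom values. Glycolysis and hypoxia genes (8 positive, 2 negative of 26, adjusted p = 0.0416, and 0.738 with an estimated correlation) lost their call without CN replicate 2 (0.0643), E1 replicate 1 (0.0630), E0 replicate 1 (0.136) or E2 replicate 2 (0.120). NF-kappaB targets, with 9 positive and 7 negative of 25, were not called (adjusted p = 0.192), Map3k8 differing by 2.64 and Tnfaip2 by -3.35. Socs1 (0.45), Tnf (1.19) and Il4 (0.08) did not pass the test of the difference, and Tnf differed by 1.72 without CN replicate 2. With the replicate number within each experiment as a block, Socs1 and Tnf passed it. Positive and negative genes adjusted over the list alone were 1 and 7 for pyroptosis and necroptosis, 9 and 1 for the unfolded protein response, 8 and 4 for remodelling, 0 and 27 for ribosomal proteins, 2 and 11 for monocyte markers, 1 and 0 for the 3 ligands, 10 and 3 for glycolysis, and 10 and 9 for NF-kappaB targets.

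Direct comparison of the 2 stimulated states, E2 versus E1, joined libraries of different experiments, so every difference also holds the difference between experiments. Mgl2 (8.25), Plet1 (8.15) and Mmp12 (7.63) were higher in E2, and Tgtp2 (-10.48), Tgtp1 (-10.38) and Gbp2 (-9.08) were higher in E1. There were 8575 genes called, 4342 higher in E2 and 4233 lower, 1941 and 1494 of them by at least 2-fold. With library totals alone, the split was 5571 and 3189 and the higher share went from 50.6% to 63.6%, the median of all genes shifting by 0.14 on the log2 scale. In this contrast 571 of 760 processed pseudogenes were called, 511 of them higher in E2, with a median of 3.10.

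Cells given IL-5 (E0) and cells given nothing (CN) were likewise cultured in different experiments. Trib3 (-3.02), Soat2 (-2.93), Atf5 (-2.92) and Lipg (-2.89) were lower in E0, as was Rpl23a (-2.32, chromosome 11, 78180932 to 78183584), a ribosomal protein gene with many retrocopies. Most of the genes with the largest positive values, Ppp1ccb (4.69), Vcp-rs (4.56), Rps3a2 (4.54) and Tpm3-rs7 (4.54), bear the names of copies of other genes. In all, 4038 genes were called, 2141 higher in E0 and 1897 lower, and 1243 were higher and 324 lower by at least 2-fold. The count was 2321 without CN replicate 2, 2427 without E0 replicate 1 and 2235 without E0 replicate 2, and with library totals alone the split was 2561 and 1270 and the higher share went from 53.0% to 66.8%. With pseudogenes, sex-linked genes and ribosomal RNA loci left out and the scaling and fit repeated, 1619 were higher in E0 and 1717 lower. Processed pseudogenes made up 489 of the 1243, and 524 of all 760 were called, with a median of 3.07, against 20.7% of protein-coding genes at the same level. Within experiments, 4.6% of them were called in E1 versus CN and 8.6% in E2 versus E0.

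**Figure D4:**
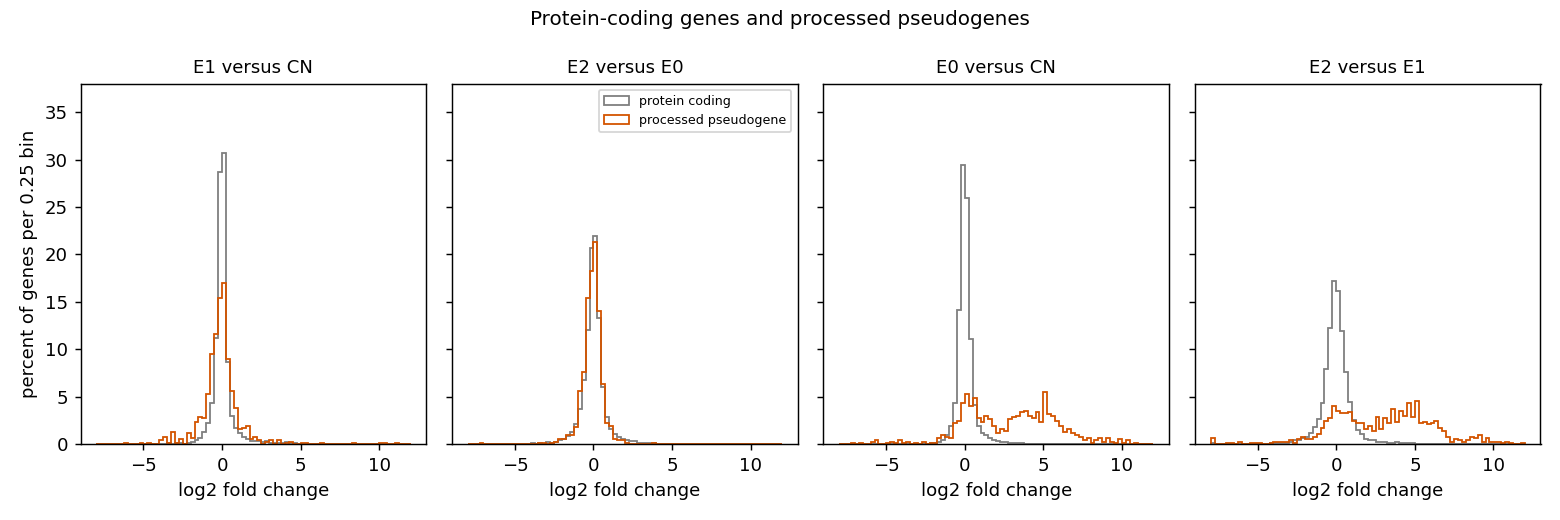
Share of genes (vertical axis, percent of each class) by log2 fold change (horizontal axis, steps of 0.25) for protein-coding genes and 760 processed pseudogenes in 4 comparisons. The pseudogenes have medians of -0.11 in E1 versus CN and -0.05 in E2 versus E0, within experiments, and of 3.10 in E2 versus E1 and 3.07 in E0 versus CN, across them.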

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

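The count without pseudogenes, sex-linked genes and ribosomal RNA loci was chosen after seeing the data, and the other alternatives were planned. At an adjusted p below 0.01, the counts of called genes were 1585 in E1 versus CN, 3251 in E2 versus E0, 2221 for the difference of responses and 1942 in E0 versus CN. With a log2 change of at least 1 they were 1171, 1771, 1969, 3435 (E2 versus E1) and 1567 (E0 versus CN), and 345 genes changed the same way in both responses, since fewer genes can pass these stricter thresholds. With the replicate number within each experiment as a block, the counts of the first 3 contrasts were 5515, 8507 and 6816. In that fit 2271 genes changed the same way in both responses and 1493 in opposite ways. It leaves fewer residual degrees of freedom than the 4 of the main model. For the 2 contrasts across experiments the block was the replicate number alone, and the counts were 8551 in E2 versus E1 and 4005 in E0 versus CN. The labels give the libraries only a common number and do not say whether they share animals. Libraries of the same number also shared their sex-linked transcripts. Deviations of same-numbered libraries from their group means correlated at 0.499 for CN and E1, 0.586 for E0 and E2 and 0.115 to 0.303 across the experiments. Over 15230 autosomal genes, a check added after seeing the data, these were 0.347, 0.393 and -0.161 to -0.0256. The cause of the higher counts was not tested. Genes called with the block and not in the model without it included Il13 (-0.46, adjusted p = 0.0122), Retnla (-0.99, 0.00024) and Mcl1 (0.29, 0.00108) in E1 versus CN, Retnla (1.01, 0.000115) and Il4 (0.14, 0.0491) in E2 versus E0, and Socs1 (0.46, 0.0017) and Tnf (1.13, 0.0124) in the difference of responses. Over all named genes and the 5 contrasts, the block added 10, 3, 12, 0 and 3 calls and ended 0. By list it called cholesterol biosynthesis lower in E1 versus CN (0.0175), ended the call of monocyte markers in E2 versus E0 (0.0720), called granule proteins negative (0.000965) and lineage transcription factors positive (0.0150) in the difference of responses, and changed no other list call. Left-out libraries gave ranges of 1904 to 2484, 3334 to 5929, 2715 to 3768, 6486 to 8451 and 2235 to 4274 called genes over the 5 contrasts in that order, 629 to 849 shared, and 15 to 17, 19 to 22 and 16 to 18 lists. The fit leaves a lone sample of a group, assumed to vary like the others. With an estimated correlation, 6, 5 and 0 lists were called instead of 15, 22 and 17. With pseudogenes, sex-linked genes and ribosomal RNA loci left out and the scaling and fit repeated, the counts were 2801, 5806, 4118, 7936 and 3336. Under DESeq2 size factors, library totals alone, other filters, DESeq2, limma-voom, robust fitting and the 4 libraries of each contrast, the total counts of called genes stayed within 1.5 times those reported. Named genes were run under DESeq2 size factors, DESeq2, limma-voom, the 4 libraries of each contrast, the block and each left-out library. No named gene called in the main fit or in the alternative changed sign there. Ccl22, called in neither, changed sign in the difference of responses without CN replicate 1. The 1 list median that reversed was that of the CCR3, CCR4 and CCR8 ligands in the difference of responses, -0.26 without CN replicate 1. With 3 genes the median is the value of a single gene, Ccl24 with 2 counts in CN when all libraries are kept and Ccl22 without this one. Named genes lost their call with a left-out library 72 times in E1 versus CN, 103 in E2 versus E0, 121 in the difference of responses, 16 in E2 versus E1 and 21 in E0 versus CN, and under other settings 15, 5, 4, 1 and 3 times. They gained one 5, 4, 5, 2 and 7 times with a left-out library and 13, 5, 18, 3 and 8 times under other settings, the block included. Depth limits the lowest genes: a library with 0 counts allows up to 0.0316 to 0.0493 CPM.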

Other observations

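Of the tests in this part, the exchange of the CN and E0 labels, the difference between the experiments for the STAT5 targets, the comparison of Retnlg and Mmp8 with the other neutrophil markers and the median of these without them were chosen after the result was seen. The tests on retrocopies were set before their own values were computed, but after Rpl23a had been seen. Rpl23a was therefore left out of the pairs of copy and parent. Cells given IL-5 and cells given nothing also differed in genes of cytokine signalling, across experiments. Of 22 STAT5 targets, 2 were higher in E0, 9 lower and 11 not called, with a median of -0.43. Cish, Socs1 and Bcl2l1 stood lower in E0 at -0.92, -1.09 and -0.53, as did Il4ra at -0.94. Mcl1, a survival gene of granulocytes, was not called in E1 versus CN (0.29) or in E2 versus E0 (-0.11), and DESeq2 called it higher in the first (adjusted p = 0.0306).

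Sex-linked transcripts separated replicate 1 from replicate 2 in every group. Xist, expressed from the inactive X chromosome of female cells (chromosome X, 103460366 to 103483254), stood at 0.0527, 0.0717, 0.193 and 0.141 CPM in replicate 1 of CN, E1, E0 and E2, and at 819, 814, 796 and 1142 CPM in replicate 2. The Y-linked Ddx3y stood at 62.5, 64.3, 82.5 and 95.6 CPM in replicate 1 and had 0 counts in replicate 2. The labels give no sex.

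Processed pseudogenes, which are retrocopies of mRNAs, differed between the experiments, with a median log2 difference between E0 and CN of 3.07. Protein-coding genes at the same level had a median of 0.159, which argues against more genomic or unspliced RNA in the second experiment. For 59 named copies of 36 ribosomal protein genes, the copy exceeded its parent in this difference by a median of 3.157 (56 pairs above 0, 3 below), while within experiments the medians were -0.07 in E1 versus CN and 0.02 in E2 versus E0. The copies thus stood higher in E0 beyond any change of their parents. That value is near the median of all processed pseudogenes, so it restates the pattern and cannot tell what raised the copies. A candidate explanation is that reads of parent genes were counted on their copies in the second experiment, as with another alignment or counting setting. Which setting, and whether the experiments were processed apart, stays open.

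The 9 STAT5 targets lower in E0 than in CN, against 2 higher (median of all 22 -0.43, with no list test for this contrast), stood beside IL-5 in the E0 medium, a cytokine that signals through STAT5. An exchange of the CN and E0 labels is argued against by the pseudogenes, over which CN correlated with E1 at 0.877 and with E2 at 0.128, a difference of 0.749, where replicates of a group correlated at 0.864 to 0.972. A difference between the experiments cannot be told apart from an effect of IL-5 (-0.431662 for the median), because no group of the first experiment received IL-5. A biological effect of IL-5 withdrawal or exposure was not tested.

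Of 16 neutrophil markers, 5 were called lower in E2 than in E0 and 11 were not called (camera adjusted p = 6.97e-06, and 0.265 with an estimated correlation). Fewer neutrophils in the E2 libraries could lower the whole list, and S100a8 and S100a9 together differed from the median of the other 8 markers at 10 CPM or more by 0.0634, and by -0.13 from that of the 6 without Retnlg and Mmp8, both within their SE of up to 0.34. Of these 6, Cxcr2 (0.07 ± 0.23) and Wfdc21 (0.21 ± 0.35) were not lower and Csf3r (-1.40 ± 0.24) and Ngp (-0.99 ± 0.16) were, so for the markers other than Retnlg and Mmp8 a lower share of neutrophils cannot be told apart from changes within eosinophils. Retnlg (-5.52 ± 0.15) and Mmp8 (-3.55 ± 0.25) fell further than the median of the other 8 markers, -0.613. They were picked as the largest falls among these markers, and eosinophils may express some of the others. The comparison therefore cannot decide whether a lower share of neutrophils is their whole cause. The depletion was against CD90 and B220 and would not remove neutrophils, Mmp8 also stands in the tissue remodelling list, and these libraries do not show how many of the markers eosinophils express themselves. A response of eosinophils to the cytokines of E2 stays open and was not tested.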
